A study of Bacillus subtilis with 15 samples.

How the data were processed

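RNA of Bacillus subtilis CU1065 and of mutants derived from it was compared on 15 two-colour arrays, 3 for each of 5 comparisons. Per the labels, cells were grown in LB to mid-logarithmic phase, each array carried the RNA of 2 strains, and the third array of each comparison had the dyes swapped. The design text gives 3 independent RNA preparations for each comparison. The labels do not say whether the fur RNA was shared between comparisons.

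The deposited values are log2 ratios of the 2 channels of each array, with scale, centring and direction not stated in the sources used here. Background correction, spot filters and within-array normalization are likewise not given in the sources used here. The median over genes lay between -0.19 and 0.27 on the 15 arrays, so not every array was centred on 0. It was 0 on replicate 2 of fur fbpABC and replicate 1 of fur. Many values equalled log2 of a ratio of 2 small whole numbers. On the 3 arrays of fur against wild type, given to 9 decimals, between 98.8 and 98.9 percent of the values were such ratios with terms of at most 10000, where chance gave 1.63 to 1.83 percent. The values were therefore read as log2 ratios of signals, while any scaling between the dyes stays unknown. On the 15 arrays, 16.3 to 38.3 percent of the values were, in lowest terms, ratios of numbers of at most 20. Such values were taken as a mark of spots near background. Brighter spots whose 2 signals are equal or share a factor are marked too, and their share is not known. Of the genes, 1211 had no such value on any array and 990 had one on 8 or more arrays. No intensities were used, and the number of arrays limits the precision.

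The direction of the ratios was settled from the deleted gene fbpB, which the array names ydbN. Its ratio was between -9.66 and -6.17 on all 6 arrays whose mutant lacks it, in both dye orientations. The deposited ratios were therefore read as mutant over reference, with swapped arrays already turned. The rule fixed beforehand used the correlation of swapped with other arrays over all genes, which averaged -0.38 and would have turned the swapped arrays. That rule was not followed because it contradicts the deleted gene, and values with the swapped arrays turned are given as an alternative. The reading rests on fbpB for fur fbpAB and fur fbpABC and is carried over to the other comparisons. In fur against wild type the fur probe was negative in both dye orientations too, though it did not pass the test. The array has no rows for fsrA, fbpA or fbpC under those names.

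The table has 4116 rows, of which 10 are control spots of viral or Escherichia coli sequence and were left out, leaving 4106 genes with 1 row each. Symbols were looked up in a RefSeq table of assembly ASM904v1, where 3036 matched directly. A further 32 were matched through an older name known from general knowledge, and 1038 keep the name of the array. No coordinates are given because the sources name no genome build.

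All 15 arrays entered one limma fit (limma 3.58.1, R 4.3.3), with a coefficient for each comparison and 10 residual degrees of freedom. No dye term was used in this fit. Genes needed a value on at least 2 of the 3 arrays of a comparison. Moderated statistics came from eBayes, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Differences between mutants were tested as 6 contrasts of the same fit. Gene lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the residuals. A negative estimate was set to 0, which makes the second test the less strict one for iron-sulphur proteins. The rotation test fry was run beside them. The 22 lists were fixed beforehand. A further 3 lists, for pyrimidine synthesis, the exopolysaccharide matrix and sulphate assimilation, were chosen after values were seen and are reported only with the closing observations.

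Genes are named by a rule fixed beforehand. It takes the deleted genes, the 10 largest rises and 10 largest falls among called genes with one sign on every array, and up to 4 members of each list with the smallest p. Where no gene was called in a direction it takes the 5 with the largest moderated statistic. For a difference it takes up to 5 called genes in each direction, or the 5 with the smallest p.

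The fit was tested on simulated data with the spread of the real genes and 50 changed genes at each of 4 folds. For fur against wild type over 4106 genes, 30 percent of 4-fold changes and 90 percent of 64-fold changes were recovered, with 5 false calls. For fur fsrA against fur these shares were 46 and 86 percent, with 4 false calls. False calls were highest for fur fbpAB against fur, at 8, and were 5 each for fur fbpC and fur fbpABC. The simulated noise was independent between genes and between arrays and held no channel effect. These shares and counts therefore do not give the error rates under the dye structure of the real arrays.

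The alternatives chosen before the data were examined were a dye term, the replicate number as a block, the arrays of the comparison alone, arrays centred on their median, arrays centred and scaled, array weights, genes measured on all 15 arrays (3934), a robust prior, a 2-fold minimum, a threshold of 0.01 and leaving out each array. Testing each row by itself was on that list too and changes nothing, since each gene has 1 row. Turning the swapped arrays was on it as well. Leaving out the values near background, with and without a dye term, was added after seeing the data. The iterative estimate of the array weights stopped short of convergence, so weights estimated gene by gene, which need no iteration, were added. List medians with each array left out and a check of pairing within one channel were added too.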

Results

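Transcript ratios were measured in Bacillus subtilis CU1065, a laboratory strain of this soil bacterium, to ask which genes respond to loss of Fur and which of these responses need FsrA or the Fbp proteins. Fur is the repressor of iron uptake genes. FsrA is a small RNA, and FbpA, FbpB and FbpC are small proteins, all made under Fur control. The fur mutant was compared with wild type, and 4 further mutants (fur fsrA, fur fbpAB, fur fbpC and fur fbpABC) were each compared with fur. Each comparison had 3 arrays, 1 of them with the dyes swapped, and between 4060 and 4105 of 4106 genes had a value on an array. All values are log2 ratios, first strain over second, with the fitted mean and its standard error (SE) from limma or the SD over 3 arrays.

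The deleted gene fbpB (ydbN) was lower in both mutants that lack it. Its log2 ratio was -6.86 ± 0.72 (SD, n = 3) in fur fbpAB against fur and -8.45 ± 1.59 (SD, n = 3) in fur fbpABC against fur. It was 0.37 ± 0.96 (SD, n = 3) in fur fsrA and 0.42 ± 1.13 (SD, n = 3) in fur fbpC, which carry the gene. The fur probe gave -1.01, -6.27 and -0.99 on the 3 arrays of fur against wild type and did not pass the test (adjusted p = 1). None of these 3 values was marked as near background, which does not exclude a dim signal in the mutant channel alone. They were negative in both dye orientations. In the comparisons where both strains lack fur, the probe was near background on 2 or 3 of the 3 arrays and had SDs of 1.92 to 3.00.

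**Figure D1:**
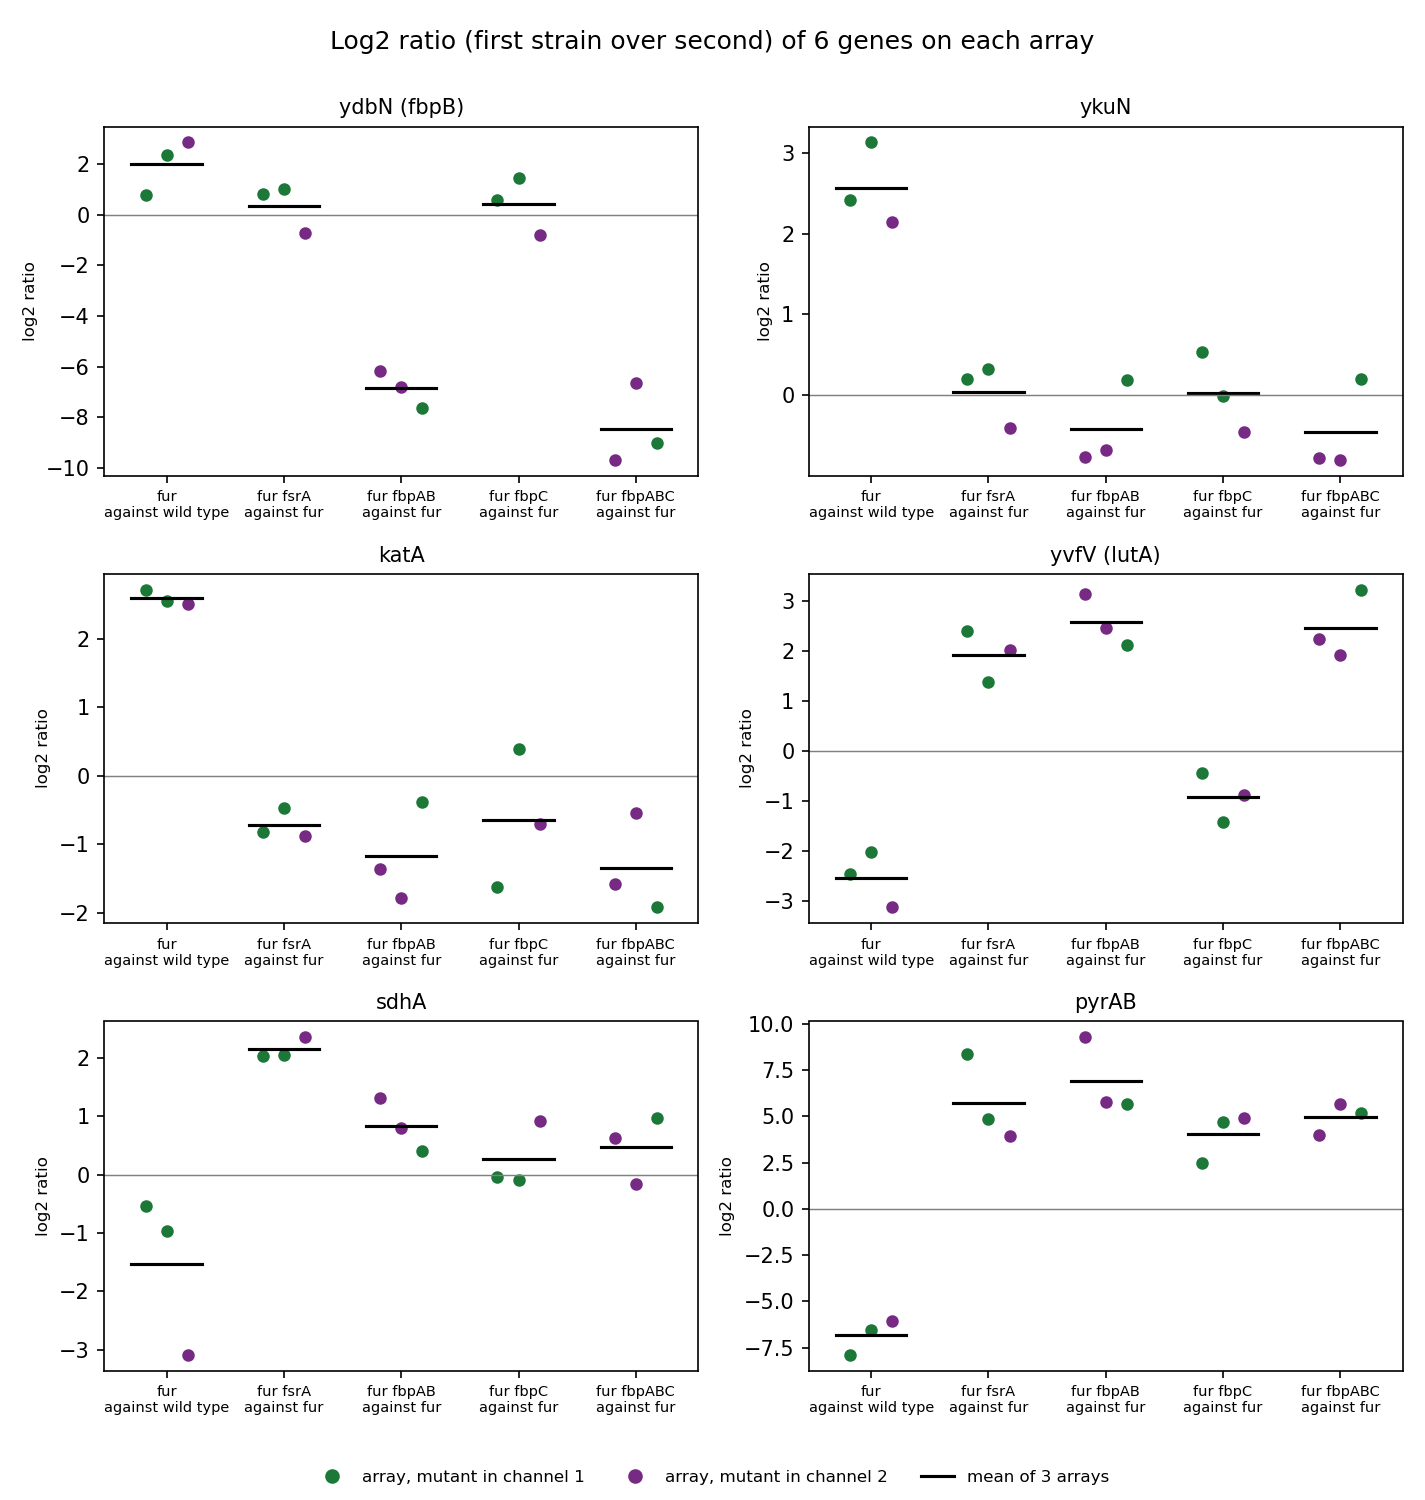
Log2 ratio (y axis) of 6 genes on each of the 15 arrays, by comparison (x axis). Points are arrays, coloured by the channel that held the mutant, and black lines are means of 3 arrays. ydbN lies at -6.17 or below on the 6 arrays of mutants that lack it, in both channels.

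Over all genes the swapped arrays ran against the other arrays of their comparison. The mean correlation across genes was -0.38, against 0.48 between the 2 unswapped arrays, and genes are not independent replicates. Among the 1211 genes with no value near background it was 0.04, but this mean covers 0.30 and 0.30 in fur fbpC and -0.22 and -0.38 in fur fsrA. Among the 990 genes near background on 8 or more arrays it was -0.53. With a dye coefficient per gene, 1712 of 4106 genes differed by channel, 1235 of them towards channel 2. The direction turned with signal. Of the 1211 genes with no value near background 250 differed and only 15 of these towards channel 2, with a median coefficient of -0.43 over the 1211, while of the 990 genes near background 727 differed, 558 of them towards channel 2, with a median of 2.48. With the swapped arrays turned, limma called 132 genes in fur against wild type and 344, 371, 302 and 257 genes in fur fsrA, fur fbpAB, fur fbpC and fur fbpABC against fur, of which 0 were shared with the genes called below.

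**Figure D2:**
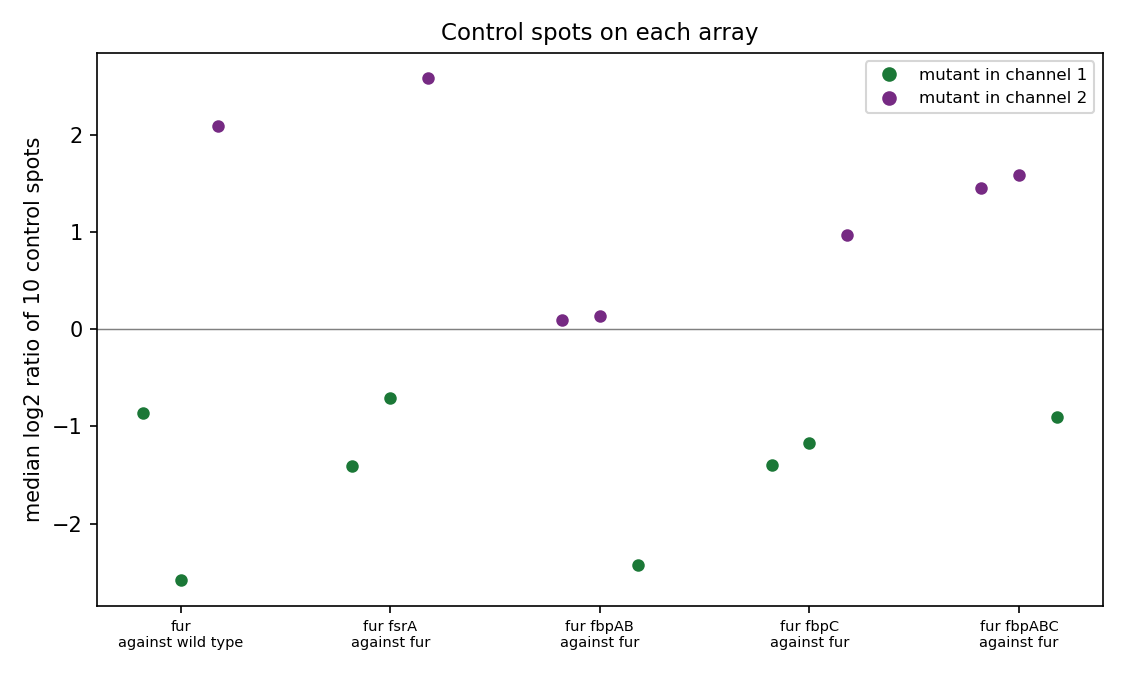
Median log2 ratio (y axis) of 10 control spots of viral or Escherichia coli sequence on each of the 15 arrays, by comparison (x axis). Points are arrays, coloured by the channel that held the mutant; the mean was 1.27 over the 7 arrays with the mutant in channel 2 and -1.43 over the 8 arrays with it in channel 1.

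In fur against wild type, single genes of iron acquisition, flavodoxin and peroxide defence rose. The bacillibactin synthesis genes dhbB and dhbE rose by 3.32 ± 0.50 (SE) and 3.20 ± 0.48 (SE), and the flavodoxin genes ykuP and ykuN rose by 2.67 ± 0.36 (SE) and 2.57 ± 0.34 (SE), with adjusted p between 0.0076 and 0.0102. Catalase katA rose by 2.59 ± 0.41 (SE), and the alkyl hydroperoxide reductase genes ahpC and ahpF rose by 1.93 and 1.95. Pyrimidine genes pyrAB and pyrC fell, at -6.83 ± 0.88 (SE) and -6.32 ± 1.02 (SE). These SEs come from the fit of all comparisons together. The SD over the 3 arrays of fur against wild type was 0.94 for pyrAB and 3.81 for pyrC. The single arrays gave -5.26, -10.55 and -3.15 for pyrC, so the size of its fall is uncertain. The genes purS and purT of purine synthesis fell too, at -3.23 and -3.09. The lactate oxidation genes lutA (yvfV) and lutB (yvfW) also fell, at -2.54 and -1.96.

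Altogether 17 genes rose and 7 fell of 4106 tested at adjusted p below 0.05 in limma. The other named rises were dhaS at 3.20, folB at 2.90, yusK at 2.73, yfiD at 2.37 and yocJ at 2.31, and the last named fall was pyrG, the CTP synthase gene, at -1.64. The ferric hydroxamate binding protein gene fhuD rose by 1.95 (adjusted p = 0.0198).

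Among 26 iron uptake genes all 26 had positive ratios, with a median of 0.94. Of these 1 rose when adjusted over all genes and 11 adjusted over the list alone, and the list passed with an estimated correlation (adjusted p = 0.000901). ybbA at 2.41 and feuB at 2.20 did not pass by themselves. All 9 other genes with a Fur box were positive with a median of 1.24, 3 rose over all genes and 7 adjusted over the list alone (adjusted p = 4.68e-07 with an estimated correlation). Of 5 lactate utilisation genes 2 fell over all genes and 3 adjusted over the list alone, with a median of -1.34 (adjusted p = 0.000214 with an estimated correlation). Of 29 genes of iron-sulphur proteins 2 fell, which are lutA and lutB again, with a list median of -0.21 (adjusted p = 0.000214 with an estimated correlation). For this list the estimate of -0.0071 was set to 0, so the preset correlation is stricter (camera, adjusted p = 0.000485).

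For bacillibactin synthesis 2 of 5 genes rose, yet the median was -0.33 and the mean 0.71 because the other members had negative ratios. dhbC, for one, was at -1.54, near background on all 3 arrays. The list passed at the preset correlation and not with an estimated one (adjusted p = 0.0617 with an estimated correlation). Calls were also lost for the PerR regulon (adjusted p = 0.0617 with an estimated correlation), purine synthesis (adjusted p = 0.0617), succinate dehydrogenase (adjusted p = 0.0633), motility (adjusted p = 0.152), the TCA cycle and Suf cluster assembly (adjusted p = 0.402 each), genes under catabolite control (adjusted p = 0.559) and ribosomal proteins (adjusted p = 0.638). Lists of haem and respiration, haem synthesis, branched-chain synthesis, other metals, nitrogen control, general stress, PBSX prophage, competence and surfactin with other antibiotics did not pass at the preset correlation.

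These counts depend on the fit. Leaving out replicate 1 or replicate 2 of fur against wild type left 0 called genes and leaving out the swapped replicate 3 left 34, while the arrays of the comparison alone gave 0 and array weights gave 133 when estimated gene by gene and 486 with an estimate that stopped short of convergence. With the dye term 33 genes were called, 24 of them in common. Without replicate 3 the lactate and iron-sulphur lists no longer passed, with medians of -0.89 and -0.20 (adjusted p = 0.121 each with an estimated correlation). The iron uptake list passed without each array, with its lowest median of 0.56 without replicate 2, and so did the other Fur box genes.

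Deletion of fsrA in the fur background gave no called gene. limma called 0 of 4105 genes, with 84 at an unadjusted p under 0.05 and a smallest adjusted p of 0.126. Array weights called 42 when estimated gene by gene and 37 with the estimate that stopped short of convergence, and the arrays of the comparison alone called 0. Values of the highest-ranked genes were 5.72 ± 2.32 (SD, n = 3) for pyrAB, 1.93 ± 0.52 (SD, n = 3) for lutA, 2.14 ± 0.18 (SD, n = 3) for sdhA and 2.24 ± 0.16 (SD, n = 3) for sdhC. The gene ywbD was at 1.11 ± 0.04 (SD, n = 3). At the lower end glpK, glycerol kinase, was at -2.43 ± 1.44 (SD, n = 3), and des, a fatty acid desaturase, was at -1.07 ± 0.27 (SD, n = 3). The others at that end were yomU at -1.46, yxjB at -1.22 and yvaW at -4.52.

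As a group the 3 succinate dehydrogenase genes were higher in fur fsrA than in fur. Their median was 2.14, and 3 of 3 passed adjusted over the list alone though 0 passed over all genes (adjusted p = 2.48e-06 with an estimated correlation). Lactate utilisation was higher with a median of 1.10 and 3 of 5 adjusted over the list alone (adjusted p = 1.71e-05 with an estimated correlation). Iron-sulphur proteins had a median of 0.30, and 3 of 29 passed adjusted over the list alone (adjusted p = 1.71e-05 with an estimated correlation). The iron-sulphur list shares lutA and lutB with the lactate list and sdhB with the succinate dehydrogenase list. The TCA cycle, which holds the sdh genes, and purine synthesis had medians of 0.82 and 1.19 and an adjusted p of 0.0494 each with an estimated correlation, while fry, which asks whether a list moves one way, gave an adjusted p of 0.189 for each. Calls were lost for haem and respiration (adjusted p = 0.0791 with an estimated correlation), branched-chain synthesis (adjusted p = 0.163), motility (adjusted p = 0.284) and ribosomal proteins (adjusted p = 0.534). With 1 array left out, succinate dehydrogenase passed each time with medians of 2.04 to 2.24. The lactate list did not pass without replicate 3, with a median of 1.12. The TCA cycle and purine synthesis did not pass without replicate 1, 2 or 3, with medians of 0.63 to 1.07 and of 0.61 to 1.67. The iron-sulphur list passed each time, and its median was 0.54 without replicate 1.

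**Figure D3:**
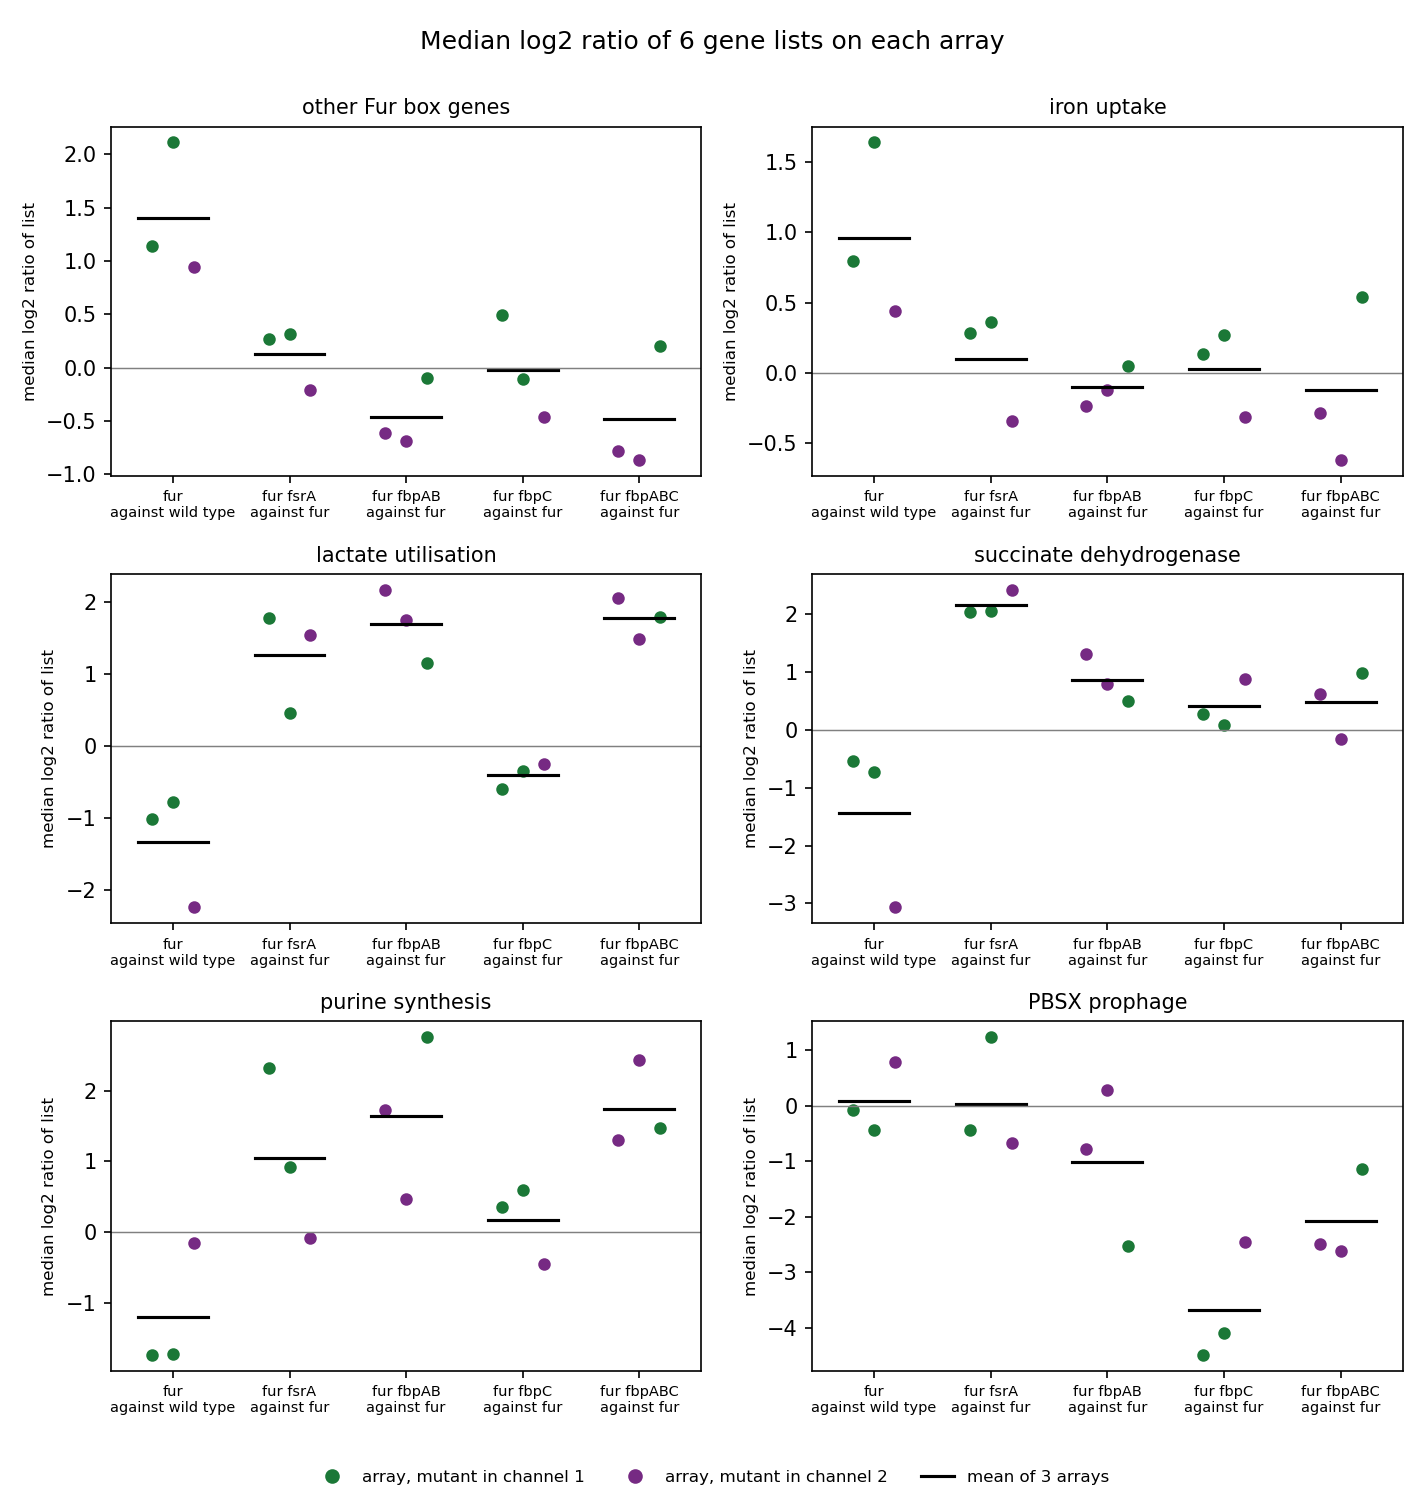
Median log2 ratio (y axis) of 6 gene lists on each of the 15 arrays, by comparison (x axis). Points are arrays, coloured by the channel that held the mutant, and black lines are means of the 3 medians. The prophage list lies at -2.46 or below on the 3 arrays of fur fbpC against fur.

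In fur fbpAB against fur, 3 genes rose and 1 fell of 4106. pyrAB rose by 6.90 ± 0.88 (SE, adjusted p = 0.0101), lutA rose by 2.58 ± 0.36 (SE, adjusted p = 0.0142) and ywbD rose by 1.77 ± 0.24 (SE, adjusted p = 0.0142). The gene that fell was the deleted fbpB. lutC at 2.38 and lutB at 1.76 missed the threshold (adjusted p = 0.0568 and 0.0742). Leaving out replicate 1 or 2 left 1 called gene and leaving out replicate 3 left 2, and the arrays of the comparison alone called 0. With arrays centred and scaled 1 gene was called, and it was a fall, so the split of 3 higher and 1 lower became 0 and 1.

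Of 5 lactate utilisation genes all 5 were positive, with a median of 1.76 and 3 passing adjusted over the list alone (adjusted p = 5.76e-07 with an estimated correlation). All 15 genes of manganese, zinc and other metal homeostasis were positive with a median of 1.30, with 0 passing over all genes and 4 adjusted over the list alone (adjusted p = 5.76e-07 with an estimated correlation). The manganese transport genes mntB and mntD were at 2.62 ± 1.09 (SD, n = 3) and 2.49 ± 0.81 (SD, n = 3). Iron-sulphur proteins had a median of 0.21 (adjusted p = 0.000142 with an estimated correlation), and purine synthesis had a median of 1.76 with 8 of 12 adjusted over the list alone (adjusted p = 0.0182 with an estimated correlation). The other Fur box genes were lower with a median of -0.47 (adjusted p = 0.00629 with an estimated correlation), a list that holds the deleted fbpB and was not tested without it. Calls were lost for haem and respiration (adjusted p = 0.145 with an estimated correlation), succinate dehydrogenase (adjusted p = 0.211), PBSX prophage (adjusted p = 0.260), Suf assembly (adjusted p = 0.289), nitrogen control (adjusted p = 0.364), the PerR regulon (adjusted p = 0.447), iron uptake (adjusted p = 0.717) and motility (adjusted p = 0.765).

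With 1 array of fur fbpAB left out, the lactate list passed each time with medians of 1.56 to 2.07. The other Fur box genes did not pass without replicate 1, 2 or 3, with medians of -0.56 to -0.29. Iron-sulphur proteins did not pass without replicate 1 or 3, with medians of 0.04 and 0.82, and purine synthesis did not pass without the same arrays, with medians of 1.54 and 1.24. Other metal homeostasis did not pass without replicate 3, with a median of 1.67, and had a median of 0.50 without replicate 2.

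Genes of PBSX, a defective prophage of B. subtilis, were lower in fur fbpC than in fur. All 29 PBSX genes had negative ratios with a median of -3.76, and 18 fell over all genes and 26 adjusted over the list alone (adjusted p = 2.21e-07 with an estimated correlation). xtmA fell by 6.45 ± 0.92 (SE), xkdE fell by 6.43 ± 0.97 (SE), xkdM fell by 4.36 ± 0.57 (SE) and the lytic enzyme gene xlyA fell by 3.99 ± 0.61 (SE), with adjusted p between 0.0105 and 0.0139. The falls were smaller on the swapped array, where the list median was -2.46 against -4.48 and -4.09, and the list passed without each array with medians of -4.32 to -3.31.

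Altogether 9 genes rose and 20 fell of 4106 in this comparison. The rises included yvfC by 4.54 ± 0.87 (SE), yveR by 3.58 ± 0.70 (SE), yvfD by 3.23 ± 0.43 (SE), yvfB by 2.65 ± 0.38 (SE) and yvfE by 2.51 ± 0.34 (SE). The competence peptide gene comS rose by 2.46, and rpsR, ssb and rpsF rose by 2.44, 2.17 and 2.11. The named falls also took in ydcL at -5.32, xkdU at -5.06, xkdO at -4.20, xkdX at -3.99, xkdW at -3.83 and xhlB at -3.80. Among list members that did not pass, srfAB and srfAD of surfactin synthesis were at 3.10 and 2.69 (adjusted p = 0.0811 and 0.0769). Calls were lost for haem and respiration (adjusted p = 0.0823 with an estimated correlation), other metals (adjusted p = 0.0845), general stress (adjusted p = 0.139), surfactin and antibiotics (adjusted p = 0.158), lactate utilisation (adjusted p = 0.220), motility (adjusted p = 0.296), and haem synthesis and ribosomal proteins (adjusted p = 0.511 each).

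Leaving out replicate 1 or 2 of fur fbpC left 0 called genes and leaving out the swapped replicate 3 left 22, and the arrays of the comparison alone called 0. Array weights called 96 genes when estimated gene by gene and 120 with the estimate that stopped short of convergence, the dye term called 44, of which 29 were in common, and a threshold of 0.01 called 0. A replicate block called 8. With values near background left out, yvfC, ydcL and xkdU narrowly missed the threshold. None of their values was marked as near background, and their ratios of 4.54, -5.32 and -5.06 stayed as they were. The mark does not see a spot dim in 1 channel alone. Whether such a dim channel sets the size of the largest falls was not tested.

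In fur fbpABC against fur 1 gene rose and 1 fell of 4105. lutA rose by 2.46 ± 0.36 (SE, adjusted p = 0.0438), and the fall was the deleted fbpB. The call of lutA was lost with a replicate block, with arrays centred or centred and scaled, with array weights, with a robust prior and with replicate 1, 2 or 3 left out, which left 1 called gene each except the array weights that stopped short of convergence, with 2, and the arrays of the comparison alone called 0. lutC at 2.25 and lutB at 1.77 missed the threshold (adjusted p = 0.0825 each).

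Lactate utilisation had a median of 1.77 with 3 of 5 adjusted over the list alone (adjusted p = 2.18e-06 with an estimated correlation). Purine synthesis was positive in 12 of 12 genes with a median of 1.65 and 6 adjusted over the list alone, iron-sulphur proteins had a median of 0.39, and both had an adjusted p of 0.00492 with an estimated correlation. Other metal homeostasis had a median of 0.74, PBSX prophage -2.05 with 18 of 29 lower adjusted over the list alone, and the other Fur box genes, which hold fbpB, -0.46, each with an adjusted p of 0.00288 with an estimated correlation. For PBSX 0 genes passed over all genes, and xkdG was at -2.20 ± 0.91 (SD, n = 3). Calls were lost for general stress (adjusted p = 0.211 with an estimated correlation), Suf assembly (adjusted p = 0.247), the PerR regulon (adjusted p = 0.412), iron uptake, nitrogen control, motility and competence (adjusted p = 0.470 each) and catabolite control (adjusted p = 0.535).

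With 1 array of fur fbpABC left out, lactate utilisation and PBSX passed each time, with medians of 1.64 to 2.05 and of -2.55 to -1.80. The other Fur box genes passed each time, with medians of -0.89 without replicate 3, -0.27 without replicate 2 and -0.22 without replicate 1. This list holds the deleted fbpB and was not tested without it, so its passing does not show a fall of the other members. Its array medians were -0.78, -0.86 and, on the swapped replicate 3, 0.20. Without replicate 2 or 3, iron-sulphur proteins did not pass, with medians of 0.20 and 0.27, nor did other metal homeostasis, with 0.86 and 1.35, or purine synthesis, with 1.20 and 1.87. The iron-sulphur median was 0.21 without replicate 1.

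Differences between the mutants were tested directly. On the unswapped arrays the mutant was in channel 2 for fur fbpAB and fur fbpABC and in channel 1 for fur fsrA and fur fbpC. In the fit without a dye term, contrasts between mutants of unlike orientation therefore hold part of any channel effect. With a dye term lutA and ywbD still passed in fbpAB minus fbpC (limma, adjusted p = 0.022 and 0.020) and in fbpABC minus fbpC (adjusted p = 0.039 each). lutA was higher in fur fbpAB than in fur fbpC by 3.49 ± 0.52 (SE, adjusted p = 0.0286) and higher in fur fbpABC than in fur fbpC by 3.38 ± 0.52 (SE, adjusted p = 0.0442). The gene ywbD differed the same way, by 2.47 ± 0.35 (SE) and 2.23 ± 0.35 (SE). The third gene in each of these contrasts was the deleted fbpB, which was also the 1 called gene in fsrA minus fbpAB and in fsrA minus fbpABC. No gene differed between fur fbpABC and fur fbpAB, where limma called 0 of 4105 with 14 at an unadjusted p under 0.05, nor between fur fbpABC and the sum of fbpAB and fbpC, with 70 at an unadjusted p under 0.05. With arrays centred, 1 gene was left in each contrast with fbpC. For fbpAB minus fbpC, leaving out replicate 3 of fur fbpC left 2 genes and leaving out any other of the 6 arrays left 0. For fbpABC minus fbpC, leaving out replicate 3 of fur fbpC left 2 and any other left 1. For fsrA minus fbpAB, leaving out replicate 3 of fur fsrA left 1 and any other left 0.

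Over the lists, lactate utilisation was higher in fur fbpAB than in fur fbpC, with a median difference of 2.08 (adjusted p = 1.11e-07 with an estimated correlation), and in fur fbpABC than in fur fbpC by a median of 2.09 (adjusted p = 9.56e-08 with an estimated correlation). Both passed without each of the 6 arrays compared. None of the list differences given here was tested with a dye term, so they may hold part of a channel effect. Iron-sulphur proteins were higher in fur fbpAB than in fur fbpC by a median of 0.67 (adjusted p = 0.0061 with an estimated correlation), and did not pass without replicate 1 or 3 of fur fbpAB. The PBSX list was higher in fur fbpAB than in fur fbpC by a median of 2.77 (adjusted p = 0.0061 with an estimated correlation), and passed without each array. Between fur fbpABC and fur fbpC the PBSX median difference was 1.58, which passed at the preset correlation and not with an estimated one (adjusted p = 0.238 with an estimated correlation). Succinate dehydrogenase was higher in fur fsrA than in fur fbpABC, with a median difference of 1.67 (adjusted p = 0.0253 with an estimated correlation), and passed in 2 of the 6 fits with 1 array left out. Against fur fbpAB its median difference was 1.22, which passed at the preset correlation and not with an estimated one (adjusted p = 0.123 with an estimated correlation). Other metal homeostasis was lower in fur fsrA than in fur fbpAB by a median of -1.29 (adjusted p = 0.00723 with an estimated correlation), and did not pass without replicate 3 of either mutant. The PBSX list was higher in fur fsrA than in fur fbpABC by a median of 2.14 (adjusted p = 0.0253 with an estimated correlation), but did not pass once any of the 6 arrays was left out. The other Fur box genes, which hold the deleted fbpB, were higher in fur fsrA than in fur fbpAB by 0.46 (adjusted p = 0.0221 with an estimated correlation) and than in fur fbpABC by 0.50 (adjusted p = 0.0253 with an estimated correlation), and passed in 0 and 2 of 6 such fits. Against the sum of fbpAB and fbpC, fur fbpABC was lower in other metal homeostasis by a median of -1.06 (adjusted p = 0.0180 with an estimated correlation) and higher in PBSX by 2.46 (adjusted p = 0.0294 with an estimated correlation), which passed in 4 and 3 of 9 such fits.

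Of the 7 genes that fell in fur, pyrAB and lutA rose in fur fbpAB and lutA rose in fur fbpABC. Independent lists would share 0.0093 and 0.0058 genes opposed in either direction, which is no value for the absence of an effect if the fur RNA was shared. In fur fsrA, where limma called no gene and 84 had an unadjusted p under 0.05, and in fur fbpC the count was 0. The correlation across genes of fur against wild type with the further mutants was -0.08 for fur fsrA, -0.36 for fur fbpAB, -0.02 for fur fbpC and -0.38 for fur fbpABC. This split follows dye orientation. Fur against wild type, fur fsrA and fur fbpC held the mutant in channel 1 on the unswapped arrays, and fur fbpAB and fur fbpABC in channel 2. With a dye term over all genes the correlations were -0.18, -0.25, -0.12 and -0.31. With a dye term and over the 1208 genes with a value on every array and none near background, these were -0.35, -0.48, -0.20 and -0.51. A simulation with no effect, over all genes and without a dye term, gave about -0.50 where the fur RNA is shared and about 0 where it is not, and the labels do not say which holds. For the fit with a dye term over the 1208 genes it gave -0.48, -0.50, -0.47 and -0.50 with shared fur RNA and between -0.03 and 0.03 without. The covariances without a dye term were -0.05, -0.26, -0.01 and -0.25, against about -0.53 simulated for shared RNA. The simulations put all residual spread into RNA preparations, with no spot noise and no channel effect. The smaller covariances therefore do not show that the fur RNA was separate. Between the further mutants, 2 genes, lutA and fbpB, changed alike in fur fbpAB and fur fbpABC, and no other pair shared a call. The shared fall of fbpB follows from its deletion in both mutants. Independent lists would share 0.00097 genes, which does not apply if both comparisons used the same fur RNA. The correlation of these 2 mutants, which share their dye orientation, was 0.55, against 0.50 simulated for shared fur RNA. With a dye term it was 0.45 over all genes. Over the 1208 genes it was 0.80 with a dye term, against 0.51 simulated for shared and 0.02 for separate fur RNA.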

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

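All tests of explanations in this part, and the exchanges of strain labels within the 5 comparisons, were chosen after related values had been seen, while the splits of arrays between mutants were set down before.

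The lactate oxidation gene lutA (yvfV) and the gene ywbD stood out because their tested difference between mutants passed the threshold. lutA differed by 3.49 between fur fbpAB and fur fbpC and by 3.38 between fur fbpABC and fur fbpC, and ywbD differed by 2.47 and 2.23. The deleted gene fbpB (ydbN) differed as its deletion requires, by -7.28 for fbpAB minus fbpC, -8.87 for fbpABC minus fbpC, 7.22 for fsrA minus fbpAB and 8.81 for fsrA minus fbpABC.

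Control spots without a B. subtilis target stood out as signal outside the main measurement. Their median ratio was 2.70 higher (log2) on the 7 arrays with the mutant in channel 2 than on the 8 arrays with it in channel 1 (exact permutation test over 6435 splits, two-sided, p = 0.000155).

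The first pattern weighed is that arrays with swapped dyes ran against the other arrays of their comparison. Ratios that run by channel and not by strain are argued against by fbpB, whose highest log2 ratio over the 6 arrays of mutants that lack it was -6.17. A channel bias that does not depend on the strain is consistent with the control spot difference of 2.70, but not as 1 shift of all genes, since the median channel coefficient was 2.48 among genes near background on 8 or more arrays and -0.43 among genes with no such value. Spots near background may carry part of it, since the mean correlation of swapped with other arrays was 0.569 higher among genes with no value near background than among genes near background on 8 or more arrays. In fur fsrA, however, the opposition stayed without such genes, at -0.22 and -0.38, and no biological explanation was tested.

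The second pattern is that a list of 10 pyrimidine synthesis genes was lower in fur against wild type, where 9 of 10 were negative, and higher in all 4 further mutants against fur. A channel bias is argued against, since 0 of the 12 arrays of the further mutants had a list median below 0. Low signal in both channels is argued against too, since 8 percent of the list values were near background. Low signal in 1 channel alone was not tested, as such spots are not marked. A low level in the fur strain alone may explain both directions, because fur over wild type plus mutant over fur would then return to 0. The list median farthest from 0 was 1.35, in fur fbpABC, and did not pass (adjusted p = 0.566 with an estimated correlation). This cannot be told apart from a separate effect in each mutant, since single genes ranged from -2.72 to 3.48 around that median.

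The third pattern is the lower PBSX prophage genes in fur fbpC, where a channel bias is argued against by the highest of the 3 list medians, -2.46, over both dye orientations. Prophage induction as a property of the fur strain is argued against as the cause of the whole fall, since fur over wild type had a list median of 0.12 with an SD of 0.44 over genes, against -3.76 in fur fbpC. Its array medians were -0.09, -0.44 and 0.78, and 2 mutants that keep fbpC had medians against fur of 0.11 (fur fsrA) and -0.95 (fur fbpAB, 25 of 29 genes negative, adjusted p = 0.260 with an estimated correlation). The list varied between arrays of these mutants, with medians of -0.45, 1.23 and -0.68 in fur fsrA and of -0.78, 0.27 and -2.52 in fur fbpAB. The lowest of these reached the -2.46 of 1 array of fur fbpC. Loss of fbpC could lower the list, which lay lower in fur fbpABC than in fur fbpAB by a median of -1.08 (adjusted p = 0.422 with an estimated correlation), but fur fbpABC departed from the sum of fbpAB and fbpC by 2.46 (adjusted p = 0.0294), which passed in 3 of 9 fits with 1 array left out. Induction in the fur cultures of this comparison alone was not tested, so the 2 cannot be told apart.

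For the 5 comparisons, the labels of 1 array at a time were exchanged, which makes 4 splits, too few for a share under 0.05. The real split gave 24 genes in fur against wild type and the highest other 6, with replicate 3 exchanged. In fur fsrA the real split gave 0 and the highest other 1, so all 4 splits gave as many, and this other was again replicate 3. In fur fbpAB, fur fbpC and fur fbpABC the real splits gave 4, 29 and 2 and the highest other 0, so 1 split gave as many. Between mutants, 10 splits of 6 arrays are also too few. fbpABC minus fbpAB gave 0, as did all 10 splits. fbpABC minus fbpC gave 3 against a highest other of 0, and fsrA minus fbpAB and fsrA minus fbpABC gave 1 each against 0. fbpAB minus fbpC gave 3, and 2 of the 10 splits gave as many, because the split by channel gave 73 genes, which points to the dye structure of the arrays. With a dye term this difference gave 4 genes.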

How the results depend on the processing

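Alternatives that left out values near background, array weights estimated gene by gene, and list medians with 1 array left out were chosen after the data had been seen and all others before. Of 56 called values of single genes, 0 changed direction under any alternative. The naming rule fixes part of this, since genes named as largest have one sign on every array. Leaving out an array could not reverse them. With the dye term 56 of 56 stayed past the threshold, with a replicate block 31, with arrays centred 45, with arrays centred and scaled 46, with either kind of array weights 54, with a robust prior 52, without values near background 53 and with the swapped arrays turned 0. A 2-fold minimum changed no count, and testing each row by itself gave no separate value because each gene has 1 row. Between 2854 and 3244 genes per comparison could be tested without values near background. Except where fewer arrays or a stricter threshold are the change itself, the cause of a changed result was not tested.

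With the arrays of the comparison alone, fur against wild type, fur fbpAB, fur fbpC, fur fbpABC, fbpABC minus fbpC, fbpAB minus fbpC, fsrA minus fbpAB and fsrA minus fbpABC gave 0 genes each. Array weights from an iterative estimate, which stopped short of convergence, gave 486 genes in fur, 37 in fur fsrA, 120 in fur fbpC and 6 in fbpAB minus fbpC. Estimated gene by gene, they gave 133, 42, 96 and 5, and 1 in fur fbpABC, with weights of 0.319 to 0.527 for the swapped arrays against up to 3.37 for others. At a threshold of 0.01, fur gave 7, fur fbpAB 1, fur fbpC 0, fur fbpABC 1, fbpABC minus fbpC 1, and fbpAB minus fbpC and fsrA minus fbpAB 0. With arrays centred and scaled, fur fbpAB, fur fbpABC, fbpABC minus fbpC and fbpAB minus fbpC gave 1 each. With arrays centred, fur fbpABC, fbpABC minus fbpC and fbpAB minus fbpC gave 1 each, the count of genes lowered in fur and raised in fur fbpABC was 0 and the overlap between mutants was 1. The dye term gave 44 in fur fbpC, 4 in fur fbpABC and an overlap of 4. A robust prior gave 1 in fur fbpABC and 1 in fbpABC minus fbpC. Without values near background fur fbpABC gave 4, and with the dye term added fur fbpAB gave 7, fur fbpABC 4 and fbpAB minus fbpC 5.

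A replicate block gave 8 genes in fur fbpC and 1 each in fur fbpABC, fbpABC minus fbpC and fbpAB minus fbpC. The mean correlation of residuals showed no pairing of arrays by replicate number across comparisons. Within one channel it was 0.36 for arrays with the same number and 0.42 for arrays with other numbers. With a dye term it was -0.013 and 0.0055 over both channels. These means cannot tell whether fur RNA was shared by number. Fur is the first strain in fur against wild type and the second elsewhere, so shared RNA would give correlations of opposite sign that partly cancel. With a dye term, single pairs ran from -0.48 to 0.47 with the same number and from -0.39 to 0.52 with other numbers. The pairing check by channel was chosen after the data had been seen.

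With an estimated correlation, 4 lists passed in fur, 5 in fur fsrA, 5 in fur fbpAB, 1 in fur fbpC and 6 in fur fbpABC.

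With the swapped arrays turned, the counts were 132 in fur, 344 in fur fsrA, 371 in fur fbpAB, 302 in fur fbpC and 257 in fur fbpABC, and 821 for fbpABC minus fbpC, 964 for fbpAB minus fbpC, 1126 for fsrA minus fbpAB and 946 for fsrA minus fbpABC. Values of genes not called reversed under it. In fur against wild type dhbC became 0.10, sdhB 0.48, sdhA 0.53, yvbY 0.15 and ykvW -0.56. In fur fsrA citB became -0.17, yvgW -0.21, xylB -0.15, xylA -0.12 and srfAD -0.00040. In fur fbpAB fur became 0.40, purF -0.0083, narH -0.0051, narI -0.15, mntC -0.11, nrgA -0.054, purQ -0.058, purS -0.15 and xlyA 0.57. In fur fbpC comGG became -0.57 and srfAB -0.14, in fur fbpABC csbD became 0.60, and in fbpABC minus fbpAB yvbW became -0.048 and yosV 0.06. With the dye term the fur value in fur fbpC became 0.13.

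Leaving out 1 array gave 0 to 34 genes in fur, 1 to 2 in fur fbpAB, 0 to 22 in fur fbpC, 1 to 1 in fur fbpABC, 1 to 2 in fbpABC minus fbpC, 0 to 2 in fbpAB minus fbpC and 0 to 1 in fsrA minus fbpAB. The lowest counts in fur and fur fbpC came without replicate 1 or replicate 2 and the highest without the swapped replicate 3. The lists past the threshold numbered 5 to 7 in fur fbpC, with 5 without replicate 2, and 8 to 14 in fur fbpABC, with 8 without replicate 2. The fur value ran from -1.42 to 1.22 in fur fbpC and from -0.50 to 2.42 in fur fbpABC, and ydbN ran from -0.10 to 1.03 in fur fbpC, each changing sign without replicate 2.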

Other observations

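The 3 lists in this part and their tests were chosen after values had been seen. Pyrimidine synthesis genes had a median log2 ratio of -2.33 in fur against wild type and of 2.80, 3.63, 1.93 and 3.84 in fur fsrA, fur fbpAB, fur fbpC and fur fbpABC against fur. All 10 genes were positive in each of the 4 further mutants. The list passed in all 5 comparisons with an estimated correlation, with adjusted p of 2.40e-06, 1.54e-10, 2.23e-11, 0.000198 and 2.83e-09. All 5 comparisons involve the fur strain, so these are not separate findings. The list passed without each array too, and its median in fur fbpC was 1.13 without replicate 2.

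Exopolysaccharide matrix genes were higher in fur fbpC against fur, with 19 of 19 positive and a median of 3.23. Of these 5 passed over all genes and 17 adjusted over the list alone (adjusted p = 7.41e-06 with an estimated correlation). In fur fsrA, fur fbpAB, fur fbpABC and fur the list did not pass (adjusted p = 0.0910, 0.0568, 0.290 and 0.554 with an estimated correlation). The difference between mutants was not tested over this list.

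Sulphate assimilation genes had a median of 2.82 in fur fbpAB and 2.62 in fur fbpABC, with 7 of 7 positive in each (adjusted p = 0.00211 and 0.00752 with an estimated correlation). These rest on replicate 1, with array medians of 4.66, 1.68 and 2.23 in fur fbpAB and of 5.29, 1.18 and 0.90 in fur fbpABC. Without replicate 1 the medians were 1.90 and 1.28 and neither list passed (adjusted p = 0.0853 and 0.0917 with an estimated correlation). In fur fsrA the median was 1.54, in fur fbpC -0.69 and in fur -0.21, and none of these passed (adjusted p = 0.0910, 0.659 and 0.554 with an estimated correlation).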
